A study of Homo sapiens with 12 samples.

How the data were processed

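RNA was measured in HCC70 cells, a human basal-like triple-negative breast cancer line, that stably carried an shRNA against LAD1 or a scrambled control shRNA. Per the labels, the cells were kept overnight without serum and then given 50 ng/ml of epidermal growth factor (EGF) for 0, 40 or 240 min, which gives 6 groups of 2 libraries each and 12 libraries in all. Poly-A selected RNA was made into libraries with a TruSeq RNA v2 kit, per the labels' protocols. The submitters' processing notes name the aligner STAR, the package DESeq2 and the genome build hg19. Their versions, the counting tool, the gene annotation, the model formula and the use of strand in counting are not given in the sources used here.

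The authors deposited a single table of 26365 gene symbols. Its signal columns hold, as tested on the values, the read count of each gene divided by a size factor per library. Dividing each column by its smallest value above 0 gave whole reads, to within 0.001, for 100% of the values in every library. The recovered totals were 12428618 to 16721013 reads per library. The deposited table also holds the authors' mean signal, a log2 fold change with its standard error, a Wald statistic (a score) and p-values with their adjusted values. The file headers do not name the contrast of that comparison. The authors' deposited log2 fold changes lay within 0.01 of the log2 ratio of the shLAD1 to the scramble mean at 0 min for 100% of the 11241 genes with a mean normalized count of at least 50.

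The design, fixed before the data were examined, gave edgeR as the test for raw counts and limma-trend for a file without them. The file holds normalized counts, so limma-trend (limma 3.58.1 in R 4.3.3, robust) on log2(normalized count + 1) was the main test. A fold change is therefore on the log2(normalized count + 1) scale, which understates changes of low genes. The fit had a mean per group over all 12 libraries, so that the groups shared an estimate of the spread, and no other term. It covered 13950 genes with at least 10 normalized counts in at least 2 libraries. Of the genes in the file, 20013 had at least 1 read. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each of the 11 comparisons. edgeR's quasi-likelihood test (4.0.16, TMM factors) on the recovered reads, added after the data were seen, called 115 genes at 40 min and 2784 at 240 min of EGF in scramble cells. The same test called 2583 genes between shLAD1 and scramble cells averaged over the 3 times.

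The 21 gene lists were fixed before the data were examined. They were tested with limma's camera at a preset correlation of 0.01, beside an estimated correlation and fry, with adjustment over the 21 lists within a comparison. The estimated correlation kept 2 list calls at 40 min of EGF in each kind of cell and 2 between 240 and 40 min, and none in the other comparisons. Named genes followed a rule set in advance. In the main comparisons it takes the 8 largest rises and the 8 largest falls among called genes with a mean log2 CPM of at least 2 whose groups did not overlap, and in other comparisons the 4 largest of each. It adds up to 4 called members of each list with the smallest adjusted p, and genes set in advance, LAD1, EGFR and FLNA among them, whatever their p. Genes outside the rule are described as chosen after their values were seen.

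The labels number the libraries 1 and 2 in every group without saying whether the numbers mark separate cultures. P-values therefore measure only the spread between these samples, which may be technical. The numbers paired the samples across groups. Deviations from the group means correlated at 0.645 to 0.734 in the 6 pairs of groups with the same shRNA and at 0.247 to 0.307 in the 9 pairs with different shRNAs. The 12 libraries were therefore also treated as 4 cell populations (shRNA by number) sampled at 3 times. The fit with the number as a replicate block is given beside results it changes. A block within each shRNA, added after the data were seen, fits the 4 populations. For the knockdown itself the populations leave 2 against 2. The labels name no second shRNA against LAD1, so an effect of LAD1 loss cannot be told from another effect of the shRNA.

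Replicates differed by more than counting noise: the chi-square per degree of freedom between the libraries of a group ran from 9.04 to 22.6, so no pair was treated as a library deposited in duplicate. The tests were tried on simulated data. On data simulated at these depths with no differences between the 4 populations, the 40 min EGF comparison in scramble cells (13864 genes) called 78 of 100 genes changed by a log2 fold of 1 and 91 of 100 changed by 2, with 6 unchanged genes called. The knockdown comparison averaged over times (13833 genes) called 89 and 95 of 100. The comparison of the 40 min responses between shRNAs (13885 genes) called 41 and 79 of 100. At 240 min (13882 genes) the same numbers were 45 and 80. With differences between the 4 populations simulated too, the knockdown comparison (13932 genes) called 95 and 98 of 100, but 538 of its 731 calls, or 73.6%, had no planted change. At 0 min (13946 genes) 63 of 227 calls, or 27.8%, had none. The EGF comparisons in scramble cells then called 0 unchanged genes, and 162 genes at 40 min and 160 at 240 min in total. The shares of 73.6% and 27.8% depend on how many genes were planted, so they are not estimates for the real calls.

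The alternatives were DESeq2 1.42.0, edgeR with relative log expression or upper-quartile factors and limma-voom on the recovered reads. Others were no filter, a mean CPM of at least 5, pseudocounts, the block, fits of only the groups compared, a minimum fold change and each library left out in turn. Total-count scaling, the populations of a single number and a mean per population were added after the data were seen. Genes below the filter were left out of the main tests. Gene positions came from a GRCh38.p14 annotation, another assembly than the authors', and served only to find neighbours and overlaps by name. Of 152 gene names looked up, 151 were found and 31 overlap another gene of the file there, such as C21orf58, HOTAIR, NR2F1, ATP13A5, SRGAP3, PTGER4 and VIM. Strand is not known to have been used, so reads of such a gene and of the gene it overlaps cannot be told apart. Reads of near-identical copies (SPRR1A and SPRR1B, KRT6A and KRT6B, ALPP, S100A7, HSPA1B, ACTG1 and ACTB, CXCL1 and CXCL2, the metallothioneins, the histone genes) could be split or lost by the counting, so their levels are uncertain.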

Results

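HCC70 cells with an shRNA against LAD1 (shLAD1 cells) or a scrambled shRNA (scramble cells) were sequenced at 0, 40 and 240 min of EGF, with 2 libraries in each of the 6 groups. No library without EGF was made at 40 or 240 min. An effect of EGF therefore cannot be told apart from the time passed or the handling since 0 min. LAD1 encodes ladinin-1, and per its title the series concerns LAD1 as a filamin binding protein that regulates actin dynamics in response to EGF. The libraries held 12428618 to 16721013 reads. Values below are mean log2 fold changes ± the standard error of the limma-trend fit, with n = 2 libraries per group and adjusted p from that fit, unless another test is named.

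LAD1 RNA was lower in shLAD1 cells at every time. At 0 min scramble cells had 6165 ± 340 normalized counts of LAD1 (SD, n = 2) and shLAD1 cells 978 ± 160, so 15.8% remained. At 40 min the levels were 6165 ± 505 and 1076 ± 148, with 17.4% remaining, and at 240 min 9648 ± 772 and 2416 ± 168, with 25.1% remaining. LAD1 fell by 2.66 ± 0.13 on the log2 scale at 0 min (adjusted p = 0.00012), with -2.52 at 40 min (adjusted p = 0.000195), and was called lower at 240 min too (adjusted p = 0.00153). LAD1 also rose between 0 and 240 min of EGF, by 0.64 ± 0.13 in scramble cells (adjusted p = 0.00987) and by 1.31 ± 0.13 in shLAD1 cells (adjusted p = 0.000431). After 40 min its change was -0.00 and 0.14, and neither was called.

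**Figure D1:**
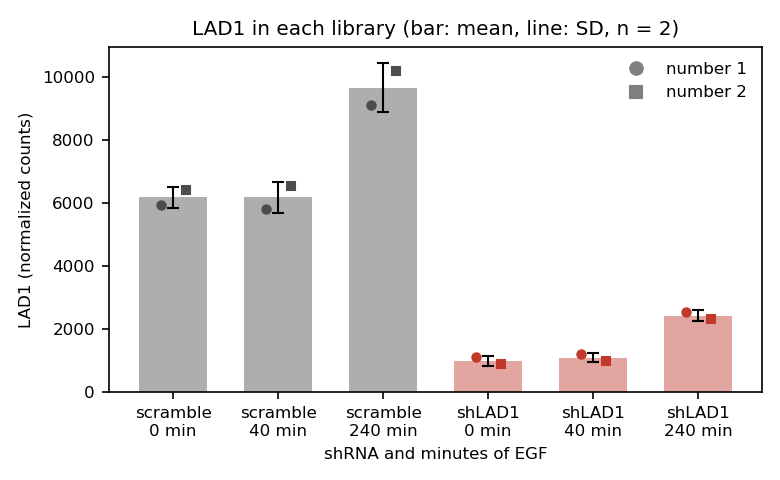
Normalized counts of LAD1 (vertical axis) in scramble and shLAD1 cells at 0, 40 and 240 min of EGF, with a point per library and the mean and SD per group. The means of shLAD1 cells, 978, 1076 and 2416, lie below those of scramble cells at each time.

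The first EGF comparison asks which genes changed within 40 min of EGF in scramble cells. Immediate early transcription factors rose most: EGR2 by 8.50 ± 0.38 (adjusted p = 1.15e-05), FOSB by 6.38 ± 0.34, EGR1 by 6.25 ± 0.27, FOS by 5.43 ± 0.12 and NR4A1 by 5.26 ± 0.34. PTGER4, a prostaglandin E2 receptor, rose by 4.13 ± 0.44, and the AP-1 subunits JUNB and FOSL1 rose by 3.85 ± 0.17 and 3.43 ± 0.30. Of 119 genes called, 118 were higher and 80 of them rose more than 2-fold. Without a block C21orf58 was the only gene called lower, at -0.52 ± 0.08 (adjusted p = 0.0173), and it overlaps YBEY. EGFR (-0.01), the EGF receptor, and the filamin FLNA (0.09) were not called.

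Of 27 measured immediate early genes 22 rose, 25 when adjusted over the list alone, IER2 by 2.57 ± 0.12. The camera test called the list (adjusted p = 1.56e-103), and adjusted p = 0.000107 with an estimated correlation. Of 22 feedback inhibitors of EGFR and ERK signalling 7 rose, 9 when adjusted over the list alone, among them the phosphatases DUSP5 (3.40 ± 0.15), DUSP2 (3.11 ± 0.22) and DUSP1 (2.32 ± 0.33) and ERRFI1 (1.97 ± 0.13), which binds and inhibits EGFR. That list kept its call, with adjusted p = 0.0223 with an estimated correlation. Of 18 genes driven by SRF and its cofactor MRTF 5 rose, 9 when adjusted over the list alone, including CYR61 (3.36), TUFT1 (2.32) and ACTG1 (1.09); adjusted p = 0.0977 with an estimated correlation. Of 29 actin cytoskeleton genes 2 rose, ACTG1 and the tropomyosin TPM4 (0.84 ± 0.12), with adjusted p = 0.509 with an estimated correlation.

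Camera called 6 other lists at 40 min. Among their called members were HBEGF (2.77 ± 0.21), a ligand of EGFR, among 10 ligands and receptors, PPP1R15A (2.35 ± 0.13) among 16 stress genes, and LIF (2.41 ± 0.28) among 17 NF-kB and cytokine genes, and 1 gene rose among 20 basal markers (0 with upper-quartile factors) and 1 among 12 heat shock genes. With an estimated correlation the adjusted p was 0.106 for the ligands and for the stress genes, 0.57 for NF-kB, 0.579 for cholesterol, 0.207 for basal markers and 0.161 for heat shock genes. The remaining 11 of the 21 lists were not called. Some list medians near 0, those of the FOXO-type, invasion, actin, ribosome and glycolysis lists, changed sign with upper-quartile or total-count scaling. The replicate block gave 202 genes, 195 higher and 7 lower, and the block within each shRNA, chosen after the data were seen, 444 higher and 86 lower. Leaving out any 1 of the 4 libraries compared gave 55 to 58.

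The 240 min comparison asks what the cells expressed once the first wave had passed. FOSL1 was the most raised, by 4.56 ± 0.30 (adjusted p = 0.0001), followed by the dehydrogenase DHRS9 (4.02 ± 0.22), the ERK phosphatase DUSP6 (3.58 ± 0.40), the focal adhesion protein TNS4 (3.50 ± 0.19) and the interleukin 6 receptor IL6R (3.44 ± 0.25). CREB5 rose by 3.26, AGPAT9 by 3.18 ± 0.39 and ANGPTL4 by 3.18 ± 0.63. Among the genes that fell were SRGAP3 (-2.92 ± 0.28), the pro-apoptotic BMF (-2.88 ± 0.38), DDIT4L (-2.81), the glutathione-degrading CHAC1 (-2.75), PPP1R3C (-2.59), KLHL24 (-2.56), COLCA1 (-2.33) and TESK2 (-2.29). Of 2813 genes called, 1635 were higher and 1178 lower, and 350 rose and 238 fell more than 2-fold. The filamin FLNA rose by 0.74 ± 0.19 (adjusted p = 0.0231), and EGFR stood at 0.59 ± 0.20 (adjusted p = 0.0663).

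Adhesion and actin genes changed between 0 and 240 min of EGF. Of 29 actin cytoskeleton genes 17 rose and 0 fell, 18 when adjusted over the list alone, for example VCL (1.42 ± 0.10), TPM4 (1.36 ± 0.12) and DIAPH1 (0.65 ± 0.07). Of 21 invasion, protease and matrix adhesion genes 9 rose, among them the integrin subunits ITGA2 (1.78 ± 0.10) and ITGA3 (1.31 ± 0.11) and the hyaluronan receptor CD44 (1.01 ± 0.07). Of 18 SRF and MRTF target genes 9 rose, with FHL2 at 1.72. Of 20 basal epithelial markers 8 rose, among them ITGA6 (1.65) and LAMB3 (0.85). These 4 lists were called by camera, and with an estimated correlation the adjusted p was 0.0904 for actin, invasion and basal genes and 0.143 for SRF and MRTF targets.

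Of 22 ribosome biogenesis genes 18 rose, 21 when adjusted over the list alone, such as WDR43 (1.15 ± 0.09), NOP2 (0.96 ± 0.10) and the pseudouridine synthase DKC1 (0.66 ± 0.07). Of 19 glycolysis and hypoxia genes 7 rose, with NDRG1 at 2.11, hexokinase HK2 at 1.61 and the glucose transporter SLC2A1 at 1.02. Of 17 NF-kB and cytokine genes 7 rose, with the chemokine CXCL1 at 2.86 and RELB at 1.54. Of 27 immediate early genes 11 were higher than at 0 min and 2 were lower, with KLF4 at 1.08 and MYC at 1.07. Of 22 feedback inhibitors 14 rose and 3 fell, with DUSP7 at 2.03. Of 10 ligands and receptors 4 rose and 2 fell: AREG rose by 3.35 ± 0.41, HBEGF by 1.89 and TGFA by 0.81, while ERBB2 fell by 0.58. Camera called the ribosome, glycolysis, immediate early and feedback lists, with adjusted p = 0.0904 with an estimated correlation for each, and NF-kB genes, with adjusted p = 0.211 with an estimated correlation. The ligand list was not called (adjusted p = 0.134).

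Of 22 genes repressed by growth factors, FOXO targets included, 12 fell and 2 rose (1 with total-count scaling), among them TXNIP (-2.13 ± 0.13), CCNG2 (-1.78 ± 0.19) and the transcriptional repressor BCL6 (-1.69 ± 0.17). Of 16 stress genes 8 fell and 1 rose, with SESN2 at -2.19, HERPUD1 at -1.44 and DDIT3 at -1.06. Of 23 mitosis genes 17 fell, 20 when adjusted over the list alone, among them TOP2A (-0.99), BUB1B (-0.80) and cyclin CCNA2 (-0.59), and of 26 replication genes 4 fell, against 6 with upper-quartile factors and 11 with total-count scaling. Camera called these lists. With an estimated correlation the adjusted p was 0.0904 for FOXO-type and stress genes, 0.143 for mitosis genes and 0.302 for replication genes.

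No list kept its call at 240 min with an estimated correlation, and fry called 16 lists. The 15 lists that camera called were also called by fry and by camera with the replicate block. The share of called genes that were higher depended on scaling: 58.1% with the deposited size factors, 45.8% with upper-quartile factors (1317 higher, 1560 lower) and 34.2% with total-count scaling (1143 higher, 2201 lower), which shifted the median of all genes by -0.127. With the replicate block 4557 genes were called and EGFR reached adjusted p = 0.00245, within a range of 5.35e-05 to 0.255 over its alternatives. Leaving out any 1 of the 4 libraries gave 1354 to 1700 genes.

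**Figure D2:**
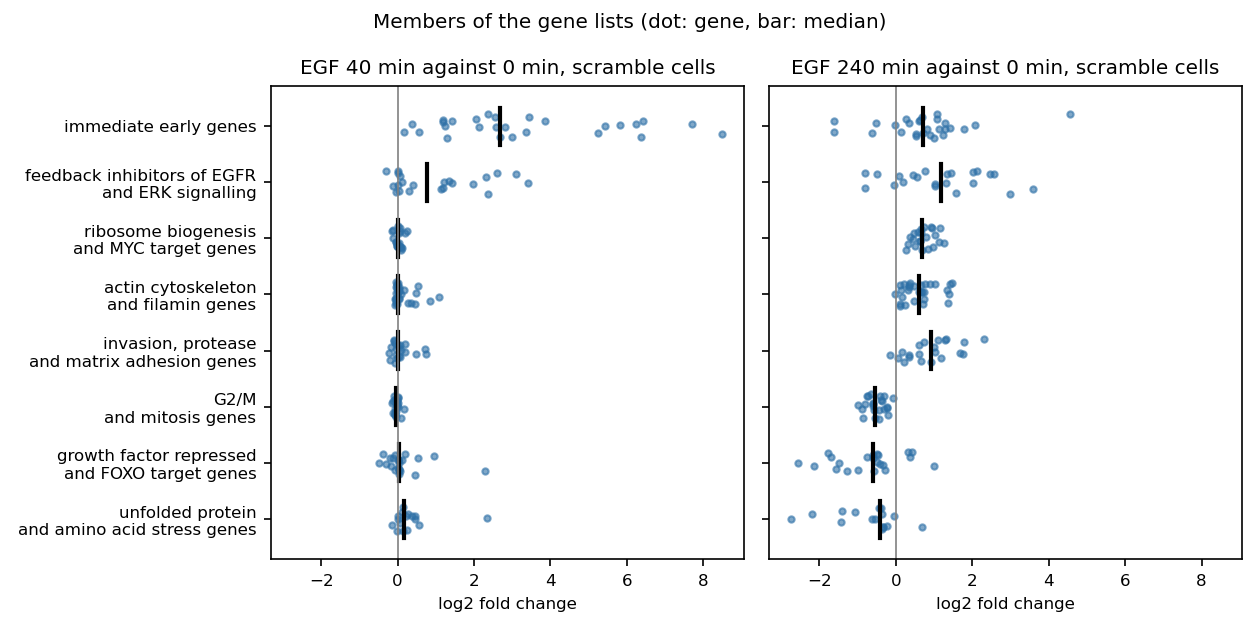
Log2 fold change (horizontal axis) of each measured gene of 8 lists after 40 and 240 min of EGF in scramble cells, with a point per gene and a black line at each list's median. Of the immediate early genes 22 rose at 40 min, and of the ribosome biogenesis genes 18 rose at 240 min.

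**Figure D3:**
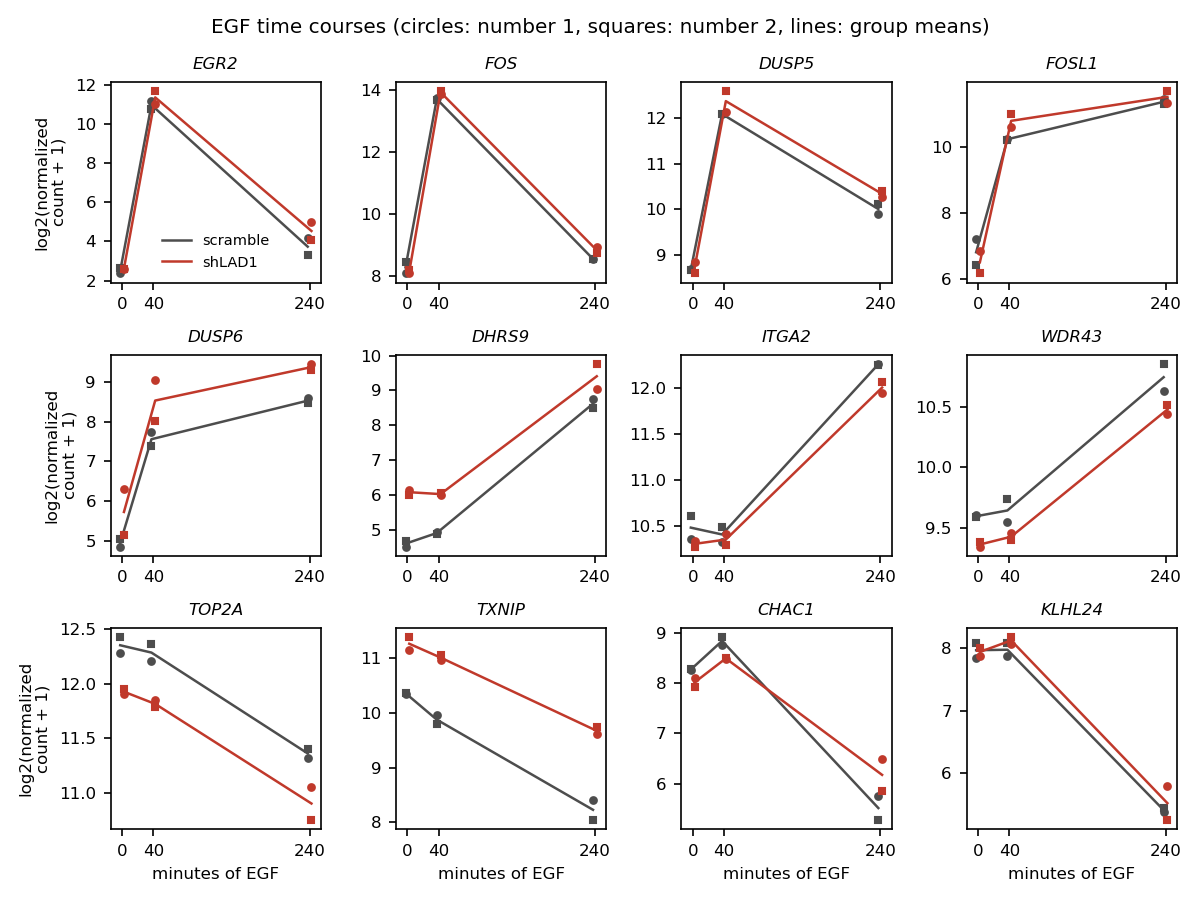
Log2(normalized count + 1) of 12 genes (vertical axes) against minutes of EGF (horizontal axes) in scramble and shLAD1 cells, with a point per library and lines through the group means. EGR2 rose by 8.50 at 40 min in scramble cells, and DHRS9 by 4.02 at 240 min.

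Between 40 and 240 min in scramble cells the early transcription factors fell and late genes rose. EGR2 fell by 7.25 ± 0.38 (adjusted p = 2.52e-05), and FOSB (-5.86 ± 0.34), EGR1 (-5.62 ± 0.27), the matricellular gene CTGF (-5.29 ± 1.30) and FOS (-5.16 ± 0.12) fell with it. DHRS9 rose by 3.72 ± 0.22, IL6R by 3.29 and AGPAT9 by 3.10, and ANGPTL4 rose too. LAD1 rose by 0.65 (adjusted p = 0.0106) and FLNA by 0.65 (adjusted p = 0.0417), and EGFR stood at 0.60 (adjusted p = 0.0676). The comparison called 2580 genes, 1417 higher and 1163 lower. Of 27 immediate early genes 20 fell and 2 rose, and of 22 ribosome biogenesis genes 18 rose; both lists kept their calls, with adjusted p = 0.028 and 0.0496 with an estimated correlation. Of 22 feedback inhibitors 7 rose, DUSP7 by 2.03, and 8 fell, with DUSP5 at -2.08, and the list was not called. Of 22 FOXO-type genes 14 fell and 1 rose, and of 16 stress genes 12 fell, with CHAC1 at -3.32 and SESN2 at -2.57. With an estimated correlation the adjusted p was 0.0779 for the FOXO-type list and 0.0764 for the stress list. With upper-quartile factors 47.8% of the genes called were higher (1248 higher, 1362 lower) and with total-count scaling 38.2% (1055 higher, 1705 lower), against 54.9%; FLNA was not called with either, nor without a filter or by edgeR with TMM factors. With the replicate block 4251 genes were called, and leaving out any 1 of the 4 libraries gave 1137 to 1541.

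Of the 118 genes raised at 40 min, 69 were also higher at 240 min than at 0 min and 6 were lower, and 71 were lower at 240 than at 40 min. Across genes, which are not independent replicates, the 40 and 240 min changes correlated at r = 0.340. Both use the same 0 min libraries, and simulated data with that shared control and no true change gave r = 0.497. Their covariance was 0.0656, against 0.0217 in the simulated data.

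In shLAD1 cells the same early factors rose after 40 min of EGF: EGR2 by 8.76 ± 0.38 (adjusted p = 6.9e-06), FOSB by 6.86 ± 0.34, EGR1 by 6.16 ± 0.27 and FOS by 5.79 ± 0.12. Of 145 genes called at 40 min 142 were higher. The cytokine LIF rose by 3.92 ± 0.28, the chemokine CXCL8 by 2.70 ± 0.40 and the EGFR ligands AREG and EREG by 2.39 and 1.94, though EREG was not called with upper-quartile factors or total-count scaling. COLCA1 (-1.16 ± 0.18), the antisense RNA HOTAIR (-1.03 ± 0.19) and OTX1 (-0.85 ± 0.13) fell. Of 27 immediate early genes 21 rose and of 22 feedback inhibitors 7 rose, with adjusted p = 0.000138 and 0.024 with an estimated correlation. Of 10 ligands and receptors 3 rose (adjusted p = 0.0558 with an estimated correlation), and of 18 SRF and MRTF targets 7 rose (adjusted p = 0.0566 with an estimated correlation). The replicate block gave 274 genes, 257 higher and 17 lower, and the block within each shRNA 561 higher and 105 lower. Without the first 0 min library 81 were called, without the second 83, and without the second 40 min library 75, and 28 were called when only these groups were fitted.

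At 240 min of EGF in shLAD1 cells FOSL1 rose by 5.02 ± 0.30 (adjusted p = 7.42e-05), CXCL8 by 3.74 ± 0.40, DUSP6 by 3.64 ± 0.40 and CXCL1 by 3.46 ± 0.24. The feedback gene PHLDA1 rose by 2.93. BMF fell by 3.19 ± 0.38, KLHL24 and DDIT4L stood at -2.42 and SRGAP3 at -2.35, each called. EGFR rose by 0.73 ± 0.20 (adjusted p = 0.0336), and FLNA stood at 0.60 ± 0.19 (adjusted p = 0.0562). Of 2585 genes called 1502 were higher and 1083 lower. Of 22 ribosome biogenesis genes 19 rose, of 29 actin genes 15 rose and of 22 FOXO-type genes 14 fell, with adjusted p = 0.0786, 0.113 and 0.117 with an estimated correlation. Of 21 invasion genes 8 rose (0.117 with an estimated correlation), of 17 NF-kB genes 10 rose and of 23 mitosis genes 14 fell (adjusted p = 0.149 with an estimated correlation for both). With upper-quartile factors 47.5% of called genes were higher (1219 higher, 1345 lower) and with total-count scaling 34.7% (1016 higher, 1915 lower), against 58.1%; the median of all genes shifted by -0.119 with total-count scaling, and EGFR lost its call with both. With the replicate block 4249 genes were called, and FLNA reached adjusted p = 0.00251, within a range of 5.71e-06 to 0.225 over its alternatives. Without the second 0 min library 1374 genes were called, without the second 240 min library 1303, and 300 when only these groups were fitted.

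The responses of both kinds of cells were compared gene by gene. All 119 genes called at 40 min in scramble cells changed in the same direction in shLAD1 cells, with r = 0.983 and a slope of 1.03, and 106 of the 118 raised genes were also called there. At 240 min 2806 of 2813 had the same sign, with r = 0.956 and a slope of 0.848. Of the genes called in both, 1283 were higher in both, 821 were lower in both and 0 were opposite. Over every tested gene r was 0.657 at 40 min and 0.843 at 240 min. These correlations are across genes, which are not independent replicates. The slopes are of shLAD1 on scramble changes, over genes picked by the same scramble changes. Picking and fitting on the same noisy values lowers a slope, so 0.848 alone does not show a weaker response in shLAD1 cells.

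The interaction asks whether the responses differed with the shRNA. LAD1 itself, at 0.67 ± 0.19 at 240 min, LIF (1.52 ± 0.40 at 40 min), IER3 (0.57 ± 0.39) and CXCL8 (1.83 ± 0.56) did not pass the main test; LIF, IER3 and CXCL8 were chosen after their values were seen. FLNA (0.03 and -0.14) and EGFR (-0.04 and 0.14) differed by less than the standard error at 40 and 240 min. limma-trend called 0 genes at both times, with 99 and 133 genes at an unadjusted p under 0.05. DESeq2 called 0 (30 and 50 unadjusted), edgeR with TMM 0 (104 and 135), voom 0 (102 and 121) and the replicate block 0. With a block within each shRNA, chosen after the data were seen, 11 genes were called at 40 min and 27 at 240 min. Without a block, limma-trend called no list member, and camera called 4 lists at 40 min and 7 at 240 min, with the lowest adjusted p 0.757 and 0.451 with an estimated correlation.

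The knockdown comparison, shLAD1 against scramble cells averaged over the 3 times, asks which genes differed with the shRNA. SPRR1B, a cornified envelope protein, rose by 4.06 ± 0.53 (adjusted p = 0.00228), S100A7 by 3.63 ± 0.20, SPRR1A by 3.15 ± 0.40 and the peptidase KLK7 by 2.30 ± 0.32. ALPP, an alkaline phosphatase, rose by 3.58, ICA1 by 3.01, the collagen COL7A1 by 2.86 and PCSK5 by 2.15. Among the genes that fell were IGSF1 (-4.30 ± 0.46), EFHD1 (-4.07 ± 0.32), KIAA1324 (-3.33 ± 0.52), ATP13A5 (-3.33 ± 0.30), NR2F1 (-2.94), PTPRZ1 (-2.84), the matrix metalloproteinase MMP7 (-2.77) and FOXL1 (-2.70). LAD1 fell by 2.39 ± 0.08 (adjusted p = 2.28e-06), while EGFR (-0.11) and FLNA (0.01) were not called. With a mean per population limma put LAD1 at -2.39 ± 0.12 (adjusted p = 0.111), which is not called. Of 2588 genes called, 1290 were higher and 1298 lower, and 203 rose and 307 fell more than 2-fold. The fold changes of the number 1 and number 2 populations correlated at 0.60 across all genes tested, and sizes differed: SPRR1B was 2.68 and 5.43, IGSF1 -3.26 and -5.34, and S100A7 3.63 and 3.62.

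**Figure D4:**
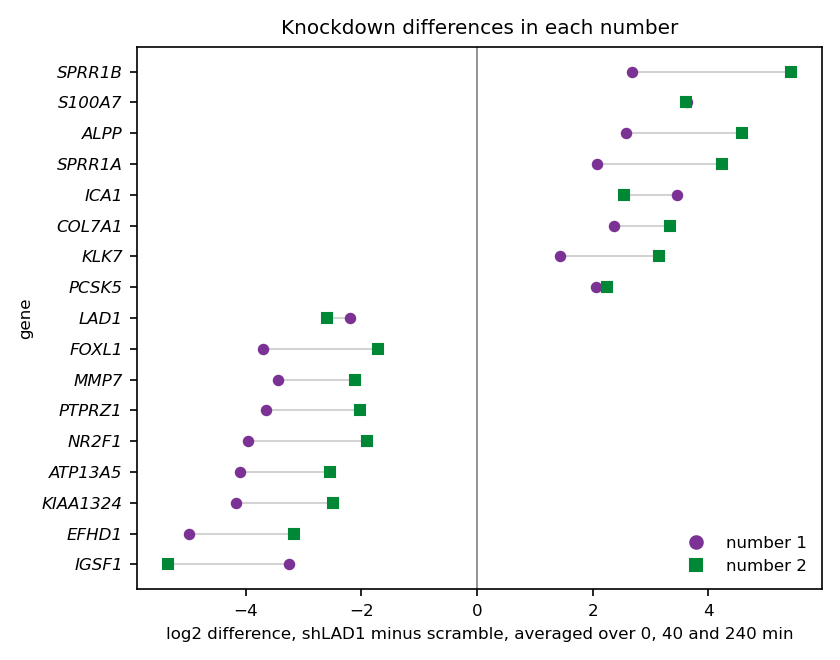
Log2 difference between shLAD1 and scramble cells averaged over the 3 times (horizontal axis) for LAD1 and the most changed genes (vertical axis), with circles for number 1 and squares for number 2. LAD1 stands at -2.19 and -2.59, and S100A7 at 3.63 and 3.62.

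Of 20 cholesterol genes 8 fell, 9 when adjusted over the list alone, among them MVD (-0.61 ± 0.14), LSS (-0.54 ± 0.08), DHCR7 (-0.43 ± 0.10) and STARD4 (-0.42 ± 0.08). Of 17 NF-kB and cytokine genes 8 fell, among them the adhesion molecule ICAM1 (-1.43), CXCL8 (-1.06), CXCL2 (-0.77) and RELB (-0.75). CXCL8 stood at -2.25, -0.42 and -0.51 at 0, 40 and 240 min. Of 23 mitosis genes 4 fell, such as TOP2A (-0.45) and PLK1 (-0.21), and of 22 ribosome biogenesis genes 4 fell, such as WDR43 (-0.24) and BOP1 (-0.22). Of 10 EGF ligands and receptors 4 rose: EPGN (1.16), EREG (0.89), HBEGF (0.60) and TGFA (0.19). Of 14 replication-dependent histone genes 3 rose, HIST1H2BD by 0.56 and HIST1H1C by 0.53. HIST1H1C differed by 0.26 in number 1 and 0.81 in number 2, and HIST1H2BD by 0.50 and 0.63. HIST1H1C also opens a stretch of 30 neighbouring genes on chromosome 6. That stretch, up to TRIM31, had a median of 0.319 in number 2 and -0.0651 in number 1. Camera called these 6 lists, but none kept its call: the adjusted p was 0.656 with an estimated correlation for cholesterol, NF-kB, ribosome, ligand and histone genes and 0.697 for mitosis genes.

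The other 15 lists were not called. Of 29 actin genes 2 rose and 3 fell, with FSCN1, which bundles actin, at 0.82 and VCL at -0.74, and of 18 SRF and MRTF targets 1 rose and 2 fell, with FHL2 at -0.53. Of 21 invasion genes 6 rose and 3 fell, with MMP13 at 2.01 and PLAUR at 0.69. Of 27 immediate early genes 5 rose, KLF4 by 0.58 and EGR1 by 0.69, and of 22 feedback inhibitors 8 rose, CBLB and DUSP10 by 0.76 each. At single times EGR1 was called at 240 min alone, at 1.53 ± 0.27 (adjusted p = 0.0484). Of 22 FOXO-type genes 6 rose and 2 fell, TXNIP by 1.16 and SESN3 at -1.40. Of 19 glycolysis genes 1 rose and 5 fell, with EGLN3 at -1.29 and LDHA at -0.19. Of 16 stress genes 2 fell (1 with TMM or RLE factors or total-count scaling), with PSAT1 at -0.67, of 26 replication genes 2 rose and 4 fell, with MCM2 at 0.23 and SLBP at -0.25, and of 24 interferon genes OAS1 rose by 0.75. Of 12 heat shock genes HSPB1 rose by 0.39.

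Lineage markers moved in both directions. Of 20 basal markers 3 rose and 1 fell, with KRT6A at 1.77, LAMB3 at 0.44 and KRT6B at -0.85. Of 17 luminal markers 5 rose and 3 fell, with the receptor KIT at -2.21 and PROM1 at -0.97. Of 9 mesenchymal markers 1 rose, COL1A1 by 1.26, and 2 fell, PDGFRA (-2.32) and VIM (-1.09). Of 7 immune and endothelial markers 2 rose, CDH5 by 1.97 and CD68 by 0.70, and HLA-DRA fell by 2.28. The fit with the replicate block called 5034 genes. Without the second scramble library of 0, 40 or 240 min 1537, 1457 or 1612 were called, and without the first shLAD1 library of 240 min 1670. On data simulated with differences between the 4 populations, this comparison called 731 genes, 538 of them with no planted change. That share depends on the number of genes planted, 100 at each size, and is no estimate for the real calls. The 4 populations leave 2 against 2, and with a mean per population limma called 0 genes, with 1798 at an unadjusted p under 0.05.

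The shRNAs were also compared at single times. At 0 min S100A7 rose by 3.71 ± 0.35 (adjusted p = 0.00382), COL7A1 by 3.26, ICA1 by 3.23 and PSCA by 2.10, and EFHD1 and IGSF1 (-4.16 each), ATP13A5 (-3.41) and the sodium channel subunit SCNN1B (-2.68) fell. ICA1 was not called at 0 min by edgeR with TMM, RLE or upper-quartile factors. At 40 min S100A7 rose by 3.58 ± 0.35, COL7A1 by 3.21, the lipase MGLL by 1.99 and PSCA by 1.95, while IGSF1 (-4.31), EFHD1 (-4.09) and ATP13A5 (-3.38) fell. At 240 min S100A7 rose by 3.58 ± 0.35, PSCA by 2.20, BNIPL by 1.67 and ADIRF by 1.59, while EFHD1 (-3.97), ATP13A5 (-3.19), the glucose transporter SLC2A6 (-2.49) and SMARCA1 (-2.33) fell. EGFR and FLNA were not called at any of the 3 times. The comparisons called 217, 230 and 133 genes: 100 higher and 117 lower, 113 and 117, and 62 and 71. On data simulated with differences between the populations, the 0 min comparison called 227 genes, 63 of them with no planted change. This share too depends on the number of genes planted. DESeq2 called 488, 516 and 370, the replicate block 1600, 1578 and 1462, and a fit of only the groups compared 1 at each time. Leaving out any 1 of the 4 libraries gave 4 to 39 genes at 0 min, 2 to 50 at 40 min and 4 to 56 at 240 min. Camera called 4, 9 and 3 lists, with the lowest adjusted p 0.60, 0.643 and 0.458 with an estimated correlation. The authors' deposited comparison had 495 genes at an adjusted p under 0.05, 235 higher and 260 lower, and 210 of the 217 called here at 0 min were among them.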

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

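The block within each shRNA and the test of the 0 min level were chosen after the results were seen. A test of the difference itself, fitted with that block, marked genes whose EGF response differed with the shRNA, 11 at 40 min and 27 at 240 min. The change in shLAD1 cells minus that in scramble cells was above 0 for 10 and below 0 for 1 at 40 min. At 240 min it was above 0 for 13 and below 0 for 14. A difference above 0 is not always a larger response. MT1G changed by -2.18 in scramble and 0.89 in shLAD1 cells at 40 min, and TXNIP by -2.13 and -1.59 at 240 min. On data simulated with the 4 populations, this fit called 87 of 100 genes whose response differed by a log2 of 1 at 40 min, against 35 without the block, and 94 against 54 at 240 min, and it also called 7 and 8 unchanged genes.

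The cytokine genes LIF and CXCL8 had larger 40 min responses in shLAD1 cells with that block. Apart from LAD1, the genes given here were chosen after their values were seen. LIF differed by 1.52, having risen by 2.41 in scramble and 3.92 in shLAD1 cells, and CXCL8 differed by 1.83, with 0.87 in scramble and 2.70 in shLAD1 cells. IER3 differed by 0.57, CSRP1 by 0.54 and the phosphate transporter SLC20A1 by 0.43. The metallothionein genes MT1G and MT1X differed by 3.07 and 0.55, and their near-identical copies make these values uncertain. ALYREF differed by -0.52.

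At 240 min the difference was 1.34 for LIF, 1.74 for CXCL8, 0.53 for IER3, 0.67 for LAD1 and 0.56 for GUCY1A3. It was -0.53 for CPA4, -0.51 for GBP2 and -0.56 for BARX2. The adjusted p of LAD1 ranged from 1.42e-05 to 1 over its alternatives, and that of LIF from 2.81e-05 to 1.

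The pattern weighed is the difference above 0 (shLAD1 minus scramble) in the 40 min response of the 10 genes. The pseudocount on low values is argued against for the 10 genes as a set: with a pseudocount of 5 the median difference was 0.676, beside 0.693 with 1. A median does not test it for a single low gene such as MT1G. A lower level at 0 min in shLAD1 cells, followed by the same level at 40 min, may account for some genes and stays open. The median difference between shLAD1 and scramble cells was -0.714 at 0 min and 0.274 at 40 min. The median of the single-gene standard errors at 40 min was 0.278, which is not the standard error of the median difference. CXCL8 stood at -2.25 at 0 min (adjusted p = 0.0345) and -0.42 at 40 min, LIF at -1.33 and 0.19 and IER3 at -0.89 and -0.32, while a lower 0 min level with the same 40 min level does not cover SLC20A1 (0.05 at 0 min, 0.49 at 40 min with adjusted p = 0.0101), SIK1 (-0.02 and 0.94, adjusted p = 0.0294) or LPIN1 (-1.02 and -0.61, adjusted p = 0.00922). An effect of LAD1 loss on the response itself stays open too, since each shRNA is represented by 2 populations. Without a second shRNA against LAD1, another effect of the shRNA cannot be told apart from it.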

How the results depend on the processing

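The block within each shRNA, total-count scaling, edgeR with TMM factors, the populations of a single number and a mean per population were chosen after the data were seen. Of 5055 values of the 247 named gene results under alternatives, 4551 kept their direction and side of the threshold, 439 lost their call, 21 gained one and 44 reversed. Those 44 are values of LAD1, EGFR and FLNA that limma-trend did not call, and the only one called under its alternative was FLNA in the averaged knockdown, at -0.12 in the number 1 populations only, against 0.01. FLNA was there -0.00279 with DESeq2 and -0.00164, -0.00554 and -0.00580 by edgeR with RLE, upper-quartile and TMM factors, and EGFR 0.00493 in the number 2 populations only. At 40 min of EGF in scramble cells LAD1 was 0.000766 and 0.00597 by edgeR with RLE and TMM factors and 0.00465 with limma-voom, and EGFR in the 240 min knockdown was 0.00339 with total-count scaling. The other reversals came without 1 library and are within the ranges given for that. Of 288 values of called lists 156 kept their call and 132 lost it. Of the 96 called lists, 90 lost their call with an estimated correlation, 41 with fry and 1 by camera with the replicate block. Of 324 values of comparisons 211 stayed within the limits set and 113 moved. The cause was not tested for the moved results below, except that a fold change minimum calls fewer genes by construction.

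With the replicate block the EGF comparisons called 202 genes (40 min, scramble), 4557 (240 min, scramble), 4251 (240 against 40 min), 274 (40 min, shLAD1) and 4249 (240 min, shLAD1), and the knockdown comparisons 5034 (averaged), 1600 (0 min), 1578 (40 min) and 1462 (240 min). With the block within each shRNA the counts of the EGF comparisons in that order were 530, 6715, 6462, 666 and 6450, and of the interactions 11 and 27. An absolute log2 fold change of at least 1 left 588 (240 min, scramble), 525 (240 against 40 min), 94 and 515 (40 and 240 min, shLAD1), 510 (knockdown, averaged) and 101, 98 and 67 (knockdown at 0, 40 and 240 min). Fits of only the groups compared called 28 and 300 (40 and 240 min, shLAD1) and 1 each for the knockdown at 0, 40 and 240 min. DESeq2 called 488, 516 and 370 for the knockdown at 0, 40 and 240 min, and limma-voom 69 at 240 min. For the averaged knockdown the number 1 populations only gave 6089 and the number 2 populations only 4543, each setting 1 population against 1 with the libraries of the 3 times as its spread, and a mean per population gave 0 (limma; 1798 at an unadjusted p under 0.05; edgeR with TMM factors on all libraries called 2583).

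Without 1 library, the lone library of a group being assumed to vary like the other groups, the counts ran from 55 to 58 (40 min, scramble), 1354 to 1700 (240 min, scramble), 1137 to 1541 (240 against 40 min), 75 to 106 (40 min, shLAD1), 1303 to 1888 (240 min, shLAD1), 1457 to 2798 (knockdown, averaged), and 4 to 39, 2 to 50 and 4 to 56 (knockdown at 0, 40 and 240 min). The knockdown value of LAD1 ran from -2.83 to -2.50, -2.66 to -2.38 and -2.08 to -1.91 at 0, 40 and 240 min. The correlation of the responses of both kinds of cells ran from 0.505 to 0.555 at 40 min and 0.737 to 0.779 at 240 min, and that of the 40 and 240 min responses from 0.272 to 0.508. With genes of mean CPM at least 5 only, these correlations were 0.893, 0.942 and 0.296. The ranges of the uncalled values that changed sign without 1 library follow. At 40 min of EGF in scramble cells they were -0.0850 to 0.0822 for LAD1, -0.10 to 0.0835 for EGFR and -0.15 to 0.33 for FLNA, and in shLAD1 cells -0.0275 to 0.31 for LAD1 and -0.32 to 0.23 for EGFR. For the knockdown, EGFR ran from -0.42 to 0.13, -0.42 to 0.0609 and -0.0793 to 0.0653 at 0, 40 and 240 min, and FLNA from -0.19 to 0.28, -0.16 to 0.32 and -0.20 to 0.00950, and from -0.0708 to 0.0911 averaged. For the interaction at 40 min LAD1 ran from -0.0260 to 0.31, EGFR from -0.31 to 0.24 and FLNA from -0.21 to 0.28, and at 240 min EGFR from -0.13 to 0.41 and FLNA from -0.38 to 0.0916.

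With an estimated correlation 2 lists were called at 40 min of EGF in scramble and in shLAD1 cells and 2 between 240 and 40 min, and 0 at 240 min in both kinds of cells and in the knockdown and interaction comparisons. Directional fry called 6 lists at 40 min in scramble cells, 7 at 40 min in shLAD1 cells, 2 for the averaged knockdown and 0 for the knockdown at single times and the interactions. AREG, CXCL2, PDGFRA, HLA-DRA, CDH5, MMP13 and MT1G were below the filter at a mean CPM of 5 and have no value there. On data simulated with differences between the populations, the 40 min EGF comparison in scramble cells called 1 of 13 genes with a mean normalized count below 100 that changed by a log2 of 1, and 72 of 87 others. The averaged knockdown called 15 of 19 such genes and 80 of 81 others.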

Other observations

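The tests chosen after the results were seen are the shuffles of the gene order, the runs between populations with the same shRNA, the test of the zinc finger genes of chromosome 19 and that of a difference of 1 population alone. After 240 min of EGF in scramble cells, protein-folding genes changed: of 12 heat shock genes 5 rose, 6 when adjusted over the list alone, with HSPA8 at 0.67 ± 0.07, HSPH1 at 0.56 ± 0.09 and the mitochondrial chaperonin HSPD1 at 0.45 ± 0.07 (n = 2 libraries per group), and 2 fell, with HSPA1B at -0.76; with total-count scaling 3 rose. Camera called the list, with adjusted p = 0.0904 with an estimated correlation. Of 14 histone genes 2 fell, HIST2H2BE (-0.64) and HIST1H2BD (-0.51), against 4 with total-count scaling, with adjusted p = 0.208 with an estimated correlation.

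Lineage and other markers moved in both directions at 240 min. Of 17 luminal markers 2 rose, the keratins KRT19 (0.55) and KRT7 (0.47), and 4 fell, with EHF at -1.28 ± 0.12 and GATA3 at -0.30 ± 0.06. Of 9 mesenchymal markers SNAI1 rose by 1.18, but with TMM or upper-quartile factors or total-count scaling 0 were called higher and 1 lower. Of 7 immune and endothelial markers 0 passed limma's test. Among 20 cholesterol genes LSS fell by 0.52, and of 24 interferon genes IFI44 fell by 0.63. These 5 lists were not called. The medians of the cholesterol and immune lists changed sign with upper-quartile or total-count scaling.

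Splits of the 12 libraries within each time tested whether any grouping calls as many genes as the knockdown did. Of 100 splits drawn from 108, 1 gave as many as the real 2588, the real split itself; the highest other, 389, was that of number 1 against number 2. Splits that break up the 4 populations gave 2 or fewer. The splits that keep the populations whole number 3, too few for a share under 0.05.

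Neighbouring genes shifted together between shLAD1 and scramble cells. Over 11148 genes in GRCh38.p14 order, the largest median shift of 30 neighbours in the number 1 populations was 0.587, on chromosome 19 between ZFP28 and ZNF256, and 0 of 200 shuffles of the gene order gave as much (highest 0.321). The same run had a median of 0.531 in the number 2 populations and of 0.0934 between the shLAD1 populations. A difference between cell populations unrelated to the shRNA may account for other runs, such as PHYH to OTUD1 on chromosome 10, at 0.499 in number 1 and 0.157 in number 2. Between the shLAD1 populations, which carry the same shRNA, the largest run was 0.563, on chromosome 10 between NUDT5 and DNAJC1, against 0.269 after shuffling, and between the scramble populations it was 0.242 against 0.166. DNA copy number was not analysed here, and the effect of the shRNA stays open.

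The chromosome 19 run between PEG3 and ZSCAN18 had a higher median in shLAD1 cells of both numbers. It holds 30 genes, with medians of 0.574 and 0.619. Of these 28 were counted as zinc finger genes by their symbols alone, a count that leaves out PEG3. In all 25 genes were higher in both, while PEG3, at the edge of the run, was at -2.70 and -3.45. The run was picked as the chromosome 19 window with the highest lower median over both numbers. That median, 0.574, is therefore no test by itself. A difference of 1 population alone is argued against by the run picked on number 1 only, ZFP28 to ZNF256. It had a median of 0.531 in number 2, where the highest shuffled value was 0.229. Genes outside a run picked for its high medians tend to lie lower. A shift of zinc finger genes as a family across the genome, of about the run's size, is argued against. The 346 outside the run had medians of at most 17.7% of it and the 219 on other chromosomes at most 11.6%. Those on other chromosomes stood at 0.0668 in number 1 and -0.00556 in number 2. A smaller shift of zinc finger genes of chromosome 19 as a group may contribute and stays open: the 127 elsewhere on it had medians of 0.216 and 0.163, at least 26.4% of the run. A second run on chromosome 19, NR1H2 to ZNF83, was also higher in both, at 0.457 in number 1 and 0.292 in number 2. Between the shLAD1 populations its median was 0.0165, and its cause was not tested. A difference shared by both shLAD1 populations, from the shRNA or from before it, stays open and was not tested.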
